A study of Apis mellifera with 180 samples.

How the data were processed

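RNA was taken from the upper midbrain, mostly mushroom bodies, of worker bees, and 180 stranded mRNA libraries were sequenced as single reads of 100 nt, per the labels' protocols. The authors deposited, for each library, whole-number read counts per gene for 15314 genes with 5 further rows for reads outside genes. CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, SAMtools 0.1.19 and HTSeq 0.6.1 were used, per the submitters' processing notes. Per the labels, reads were mapped to the bee assembly Amel 4.5 and, separately, to the DWV genome; the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes were not told apart. Of each library's reads in the count files, a median of 69.6% fell in genes, 27.4% in no gene, 0.235% in more than 1 gene and 2.65% aligned to more than 1 place. These further rows were left out of library sizes and tests, and genes with near-identical copies are uncertain for that reason.

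Groups were taken from the labels of challenge, time and colony. Libraries with a DWV share of reads of at least 0.005 were left out of all comparisons but the one on DWV. By the share in the labels this took out 28 libraries, whereas the design text of the series names 26. The lowest share among the 28 was 0.0498 and the highest among the other 152 was 0.00151, so any threshold between these gives the same 28. Bees were assigned to treatments at random and controls and challenged bees are paired, per the labels and the series' design text. The labels give the libraries as separate samples but do not say which of them came from the same dish of bees, so p-values measure the spread between these samples. A further number in the library titles is shared within pairs, and some of these numbers recur at other times in the same colony. What it stands for is not given in the sources used here, and no test used it. The exclusion left 65 complete pairs and broke 22, so the pair was not in the model, and a fit with the pair as a block on complete pairs was run beside it. Checked on residuals, the median correlation within a pair was 0.0247 against -0.00989 between other libraries of the same groups, 23 of 65 pairs exceeded 0.1, and 12 challenged libraries correlated best with their own partner against 9 by chance. The pairing is therefore taken from the design text, not from these correlations.

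Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 18 groups with a minimum count of 10, which left 11482 genes for the 152 libraries and 11386 for all 180. Normalisation was by TMM, and a quasi-likelihood model (estimateDisp, glmQLFit, glmQLFTest) with a mean per group was fitted to all groups together, so that they shared 1 estimate of the spread. Challenge effects were averaged over colonies with equal weight. Differences of the challenge effect between times and between colonies, differences between colonies and differences between times among controls were F-tests with 2 degrees of freedom. The DWV comparison added a term for a rich library to the 18 means. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the F statistic, and CPM values are TMM-normalised, except that the limit of 10 CPM of GB51815 used counts over the library total. Set tests used camera of limma 3.58.1 with a preset and an estimated correlation. Correlations and the difference in reads aligned to more than 1 place were tested with 100000 random permutations, whose smallest possible p is 1e-05.

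The rule for naming genes, fixed before the data were examined, asked for genes with names in the reference. None of the 15314 identifiers matched the gene table supplied, which is of the assembly Amel_HAv3.1, so the rule fell back to the 2 higher and 2 lower genes with the smallest p in each comparison, and to all genes called in the 2-degree tests where these were 5 or fewer and otherwise 2. For the same reason the 22 gene lists fixed beforehand, cell type markers included, were not tested (0 of 22).

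The procedure was tested on simulated counts with the library sizes and means of the data and 200 changed genes. For challenge at 30 min, 80.0% of genes changed 1.25-fold, 87.8% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold were recovered among 11359 genes, with 3.19% false calls. For the difference between times these were 62.0%, 81.6%, 92.0% and 100%, with 5.11% false calls, and for the DWV comparison, among 11317 genes, 84.0%, 100%, 94.0% and 100%, with 5.5% false calls. Simulated contrasts with no change gave 0 calls. The simulated counts were drawn independently around 1 mean per gene, with no effect of colony, pair or lane, so these rates may not hold for the data. The lowest chi-square per degree of freedom between 2 libraries of a group was 6.99 over 810 pairs. Depth did not fall under 9362837 gene counts in any library, so 1 count corresponded to at most about 0.1 CPM.

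Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 50% of libraries, all 180 libraries, the pair as a block, complete pairs alone, the lane label as a term, each kind of lane label alone, each colony left out, and for DWV the share of reads as a continuous term. Chosen after the data were seen were leaving out the 14 libraries with over 10 CPM of GB51815, leaving out each library, thinning all libraries to the lowest total, the percentage of mapped reads as a covariate, and looking up the genes called without a colony in that colony. Random regroupings of libraries, 99 for each comparison and 79 for DWV, were refitted in the same way. Challenge labels were shuffled within time and colony, and colony labels within time and challenge. Time labels were shuffled within colony and challenge, and DWV richness within each of the 18 groups.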

Results

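The data were read counts per gene from 180 RNA-seq libraries of worker honey bees (Apis mellifera). The libraries were made from the upper part of the midbrain, which holds mostly the mushroom bodies, the paired centres of the insect brain that serve learning and sensory integration. Small groups of young workers had met either an unrelated intruder bee for 5 min (challenged) or a small tube (control), and the labels give a time of 30, 60 or 120 min. The workers came from 3 colonies, cR02, cR03 and cR21, each headed by a queen inseminated by a single drone, so that workers of a colony were closely related. Challenge, time and colony formed 18 groups of 10 libraries. Deformed wing virus (DWV), an RNA virus of honey bees, made up at least 0.005 of the reads of 28 libraries according to the labels. These 28 were left out of the comparisons of challenge, colony and time, which left 152 libraries, 76 control and 76 challenged, with 6 to 10 per group. The total gene count ranged from 9362837 to 27550505 per library over all 180 and was at least 11792589 among the 152. No 2 libraries of a group agreed within sampling noise. Gene identifiers are given as deposited, without names.

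Whether an encounter with an intruder changed transcript levels was asked first at 30 min, with 26 challenged and 26 control libraries. Of 11482 genes tested, 22 passed an adjusted p of 0.05, of which 19 were higher and 3 lower in challenged bees. In normalised read counts relative to library size (CPM), GB41700 rose from 26.4 ± 6.81 CPM (SD, n = 26) in controls to 46.1 ± 11.7 CPM (SD, n = 26), a log2 fold change of 0.81 ± 0.11 (SE, adjusted p = 1.22e-07). GB50091 rose from 99.8 ± 39.2 to 193 ± 67.8 CPM (SD, n = 26 each), a log2 fold change of 0.97 ± 0.16 (SE, adjusted p = 9.07e-05). GB40340 fell by 0.38 ± 0.09 on the log2 scale (SE, adjusted p = 0.0179) and GB49758 fell by 0.28 ± 0.06 (SE, adjusted p = 0.0179). The 19 higher genes had a median log2 fold change of 0.35, and 1 of them changed more than 2-fold. Tested in a colony left out of the selection, 14 of the 19 genes called without cR03 had the same direction in cR03, 4 of them at an unadjusted p below 0.05 (0.475 by chance), and all 12 called without cR21 had it in cR21, 10 of them below 0.05 (0.3 by chance). The 1 gene called without cR02 had the same direction there. With the pair as a block, 16 genes passed, and neither GB40340 (adjusted p = 0.0869) nor GB49758 (adjusted p = 0.254) was among them. Without colony cR02, 1 gene passed, and without cR21, 12 passed. All of the cR03 libraries at this time carried the lane label L00M, and no gene passed among the libraries with that label by edgeR (728 genes at an unadjusted p below 0.05).

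**Figure D1:**
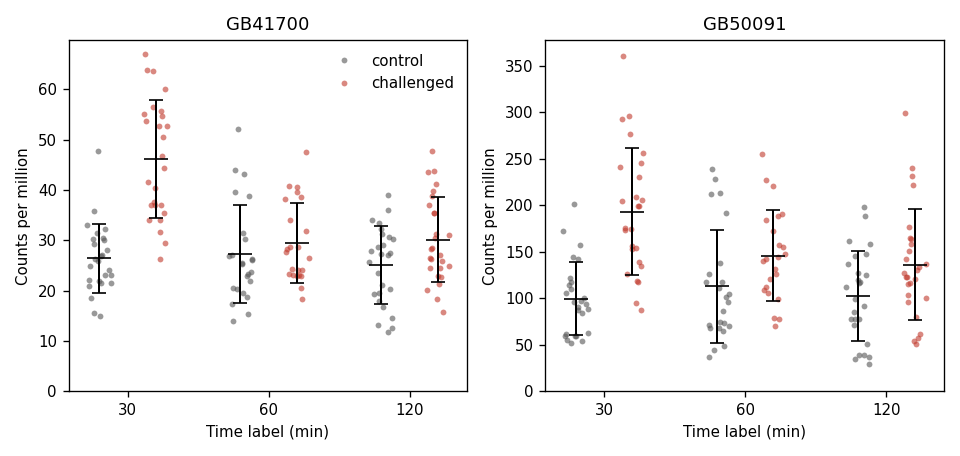
CPM of GB41700 and GB50091 (y axes) in each of the 152 libraries, by time label in min (x axes) and challenge; points are libraries, and bars are the mean ± SD. At 30 min the mean of GB41700 was 46.1 CPM in challenged and 26.4 CPM in control bees, and that of GB50091 was 193 and 99.8 CPM.

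At 60 min, with 23 challenged and 24 control libraries, no gene passed the threshold in edgeR. The lowest adjusted p was 0.111, and 642 genes had an unadjusted p below 0.05. DESeq2 called 3 genes, limma-voom called 0, and edgeR on all 180 libraries called 5. The gene with the smallest p, GB50196, had a log2 fold change of 3.26 ± 0.71 (SE), with medians of 0.218 CPM in challenged and 0.232 CPM in control bees and 267.7 CPM in the highest challenged library. GB49099 had a log2 fold change of -0.18 ± 0.05 (SE, adjusted p = 0.80). Of the 19 genes that were higher at 30 min, 17 had positive values at 60 min, with a median of 0.09, and none passed by edgeR. As a set these 19 genes stood above the other genes at 60 min with a preset inter-gene correlation (camera, adjusted p = 4.34e-07), but adjusted p = 0.112 with an estimated correlation. The set was chosen on libraries of 30 min, which share none with the libraries of 60 min. Control and challenged libraries had different first index sequences in their titles at both times, however, and most of these sequences recurred.

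At 120 min, with 27 challenged and 26 control libraries, 27 genes passed, 17 higher and 10 lower in challenged bees. GB47624 rose from 20.3 ± 7.12 CPM (SD, n = 26) to 29.9 ± 14.5 CPM (SD, n = 27), a log2 fold change of 0.57 ± 0.11 (SE, adjusted p = 0.00472). GB47625 rose from 45.3 ± 10.2 to 61.0 ± 28.1 CPM (SD, n = 26 and 27), a log2 fold change of 0.43 ± 0.09 (SE, adjusted p = 0.00472). With single libraries left out, the log2 fold changes of GB47624 and GB47625 went down to 0.44 and 0.32. Their highest adjusted p in edgeR, 0.0209 and 0.0300, came without challenged cR02 replicate 6. GB42549 fell by 5.19 ± 0.92 on the log2 scale (SE, adjusted p = 0.00114) and GB51815 fell by 5.31 ± 0.99 (SE, adjusted p = 0.00195). The medians of GB51815 were 0.257 CPM in challenged and 0.443 CPM in control bees, while the highest libraries reached 33.7 and 381.4 CPM. Without control cR02 replicate 5 the log2 fold changes were -3.0 for GB42549 and -3.23 for GB51815, and without control cR03 replicate 4 that of GB51815 was -3.23, none of these past the threshold. Over 10 CPM of GB51815 were present in 1 of 27 challenged and 4 of 26 control libraries, with an odds ratio of 0.217 (95% interval 0.00415 to 2.41, two-sided Fisher's exact test, p = 0.192), so that neither a difference nor its absence was shown. Without the 14 libraries that held over 10 CPM of this gene at any time, 4 genes passed, all 4 of them higher in challenged bees. With the pair as a block 5 genes passed, of which 2 were among the 27, with GB47624 and GB47625 (adjusted p = 0.0571 for each), GB42549 (adjusted p = 0.232) and GB51815 (adjusted p = 0.265) not among them, and limma-voom called 0 genes (1619 at an unadjusted p below 0.05). Of the 8 genes called without cR03, 4 had the same direction in cR03, 2 of them at an unadjusted p below 0.05 (0.2 by chance), and without cR21 no gene passed by edgeR (885 at an unadjusted p below 0.05). No gene called at 30 min was called at 120 min by edgeR, but chance alone would give only 0.028 shared higher genes. At an unadjusted p below 0.05, 12 of the 19 genes higher at 30 min were higher at 120 min too. Of the 19 genes higher at 30 min, 17 had positive values at 120 min, with a median of 0.15 (camera adjusted p = 8.41e-08 with a preset and adjusted p = 0.112 with an estimated correlation).

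**Figure D2:**
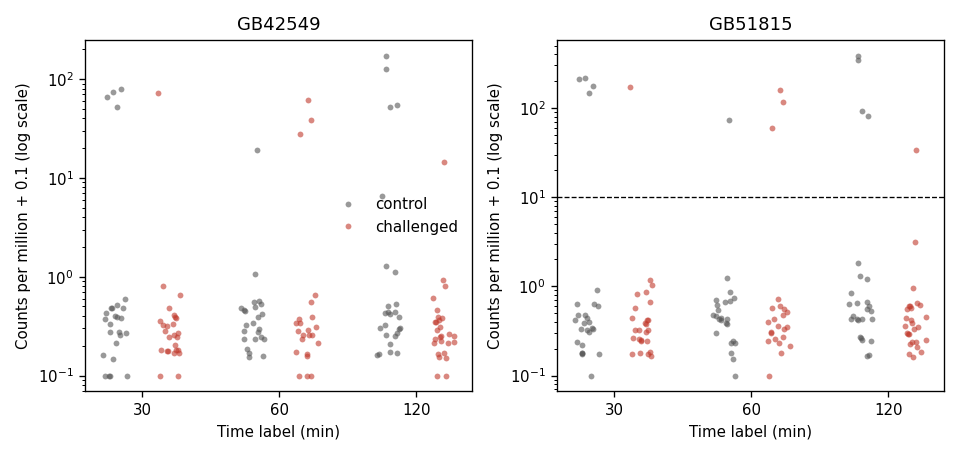
CPM plus 0.1 of GB42549 and GB51815 (y axes, log scale) in each of the 152 libraries, by time label in min (x axes) and challenge; the dashed line marks 10 CPM of GB51815. Of the 152 libraries, 14 lay above the line, 9 control and 5 challenged, and the other 138 held at most 3.03 CPM.

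Over all times, 153 genes differed between challenged and control bees, 105 higher and 48 lower. GB40074 rose by a log2 fold change of 0.52 ± 0.07 (SE, adjusted p = 1.61e-06), with means of 121 ± 45.5 and 192 ± 72.0 CPM at 30 min, 136 ± 48.7 and 186 ± 51.6 CPM at 60 min, and 134 ± 45.0 and 191 ± 73.8 CPM at 120 min in control and challenged bees (SD, n = 26, 26, 24, 23, 26 and 27). GB46492 rose by 0.20 ± 0.03 (SE, adjusted p = 4.07e-06). GB44909 fell by 0.06 ± 0.01 (SE, adjusted p = 0.00502) and GB53695 fell by 0.12 ± 0.03 on the log2 scale (SE, adjusted p = 0.0112). The changes were small, with a median log2 fold change of 0.16 for the higher and -0.12 for the lower genes, and 3 of the 153 genes exceeded 2-fold. With the pair as a block 56 genes passed, 46 higher and 10 lower, of which 47 were among the 153. Without colony cR02 293 genes passed, without cR03 5 and without cR21 8. Of the 293, 219 had the same direction in cR02, but only 11 of them at an unadjusted p below 0.05, against 7.3 by chance. In cR03 4 of the 5 had it, 3 of them below 0.05 (0.125 by chance), and in cR21 all 8 had it, 7 of them below 0.05 (0.2 by chance).

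Whether the response to the challenge changed with time was tested with both differences from 30 min at once. By this test 3 genes passed: GB42549 and GB51815 (adjusted p = 0.000189 for each) and GB42557 (adjusted p = 0.00253). The log2 fold change of GB51815 was -2.49 ± 1.58 at 30 min, 3.58 ± 1.03 at 60 min and -5.31 ± 0.99 at 120 min (SE). That of GB42557 was 0.27 ± 0.44, 1.59 ± 0.48 and -1.96 ± 0.43 (SE). No gene passed with the pair as a block, with limma-voom, or without the 14 libraries with over 10 CPM of GB51815, with 479, 593 and 621 genes at an unadjusted p below 0.05. The 19 genes higher at 30 min had a median difference of -0.25 on the log2 scale between 60 and 30 min. Of these, 14 passed for that difference when adjusted over the list alone, a list chosen on the same 30 min libraries, and 0 passed over all genes tested by edgeR. GB41700 had a log2 fold change of 0.09 ± 0.12 at 60 min and 0.28 ± 0.11 at 120 min (SE).

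Whether it differed between colonies was tested in the same way, and 5 genes passed: GB41339 (adjusted p = 0.0118), GB42467 and GB45147 (adjusted p = 0.0140 for each), GB43422 (adjusted p = 0.0175) and GB55613 (adjusted p = 0.0316). GB41339 at 120 min had log2 fold changes of 2.80 ± 0.91 in cR02, -3.21 ± 0.78 in cR03 and 1.59 ± 0.80 in cR21 (SE). GB42467 at 30 min had 2.31 ± 0.91 in cR02, -3.41 ± 0.73 in cR03 and -0.25 ± 0.88 in cR21 (SE), and in cR03 control replicate 2 held 109 CPM of it and the next library 2.19 CPM. No gene passed with the pair as a block or with limma-voom, with 942 and 844 genes at an unadjusted p below 0.05. Tested within each colony, 6, 5 and 4 genes passed at 30 min in cR02, cR03 and cR21, and 4, 0 and 3 passed at 60 min. For 11 of these 22 calls, 1 library held over 50% of the gene's CPM summed over that colony and time. Among them, chosen after their values were seen, were GB50423 at 60 min in cR21 (log2 fold change -8.60 ± 1.2, SE, adjusted p = 5.09e-07), with 99.7% in control replicate 3, and GB50196, with 95.7% in challenged replicate 4 at 60 min in cR02 and 98.2% in challenged replicate 7 at 30 min in cR21. At 120 min 0 genes passed in cR02, 193 in cR03 and 91 in cR21, with 306, 1466 and 1960 genes at an unadjusted p below 0.05 in edgeR. This difference in counts was not itself tested. The 317 genes called at 120 min from cR03 and cR21 together had the same direction in cR02 in 62.1% of cases, and 9 of them had an unadjusted p below 0.05 in that direction, against 7.93 from chance.

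**Figure D3:**
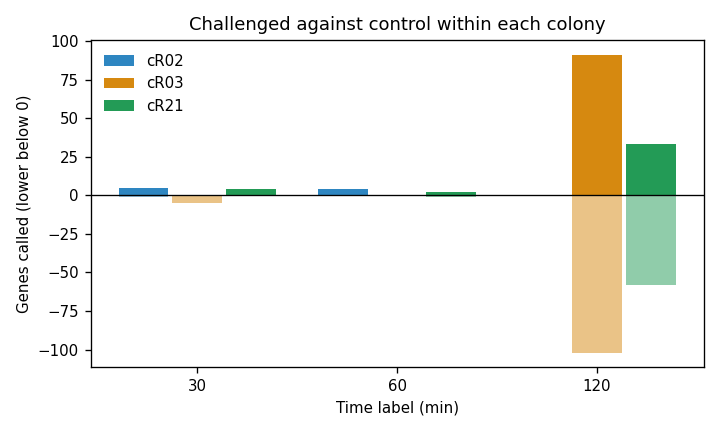
Number of genes that passed an adjusted p of 0.05 for challenged against control bees within each colony (bars, y axis), by time label in min (x axis); full colour above 0 counts genes higher and pale colour below 0 genes lower in challenged bees. At 120 min 91 genes were higher and 102 lower in cR03, 33 were higher and 58 lower in cR21, and none passed in cR02.

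Colonies differed in 9582 of the 11482 genes (83.5%). GB49219 stood at 184 ± 60.6 CPM in cR03 (SD, n = 56), 0.248 ± 0.263 CPM in cR02 (SD, n = 41) and 0.131 ± 0.198 CPM in cR21 (SD, n = 55). GB46276 stood at 386 ± 35.1 CPM in cR02, 62.3 ± 6.97 CPM in cR03 and 108 ± 18.2 CPM in cR21 (SD, n = 41, 56 and 55). Between pairs of colonies, 7069 genes differed between cR02 and cR03, 6372 between cR02 and cR21 and 7720 between cR03 and cR21, of which 296, 339 and 400 exceeded 2-fold. The first principal component held 17.0% of the variance, and colony accounted for 92.9% of it. Lane labels were spread unevenly over colonies: all 20 cR03 libraries at 30 min and all 20 at 60 min carried L00M, while 19 of the 20 cR21 libraries at 30 min and all 20 at 60 and at 120 min carried single lanes. With the lane label as a term, 7418 genes differed between colonies. Mean depth also differed, from 14139300 gene counts in cR21 to 18741800 in cR03, and 9288 genes differed with all libraries thinned to the lowest total.

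Among controls, 19 genes differed between times. GB46740 stood at 23.0 ± 2.03 CPM at 30 min, 21.5 ± 2.06 CPM at 60 min and 20.1 ± 1.98 CPM at 120 min (SD, n = 26, 24 and 26, adjusted p = 0.0221). GB42549, with medians of 0.275, 0.233 and 0.305 CPM, passed as well (adjusted p = 0.0221). Between 30 and 120 min 38 genes passed, 5 higher and 33 lower at 120 min, and between 30 and 60 min none passed by edgeR (676 at an unadjusted p below 0.05). With the lane label as a term 2 genes passed, and DESeq2 called 34.

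Libraries rich in DWV were compared with the others over all 180 libraries, with the 18 groups in the model. Of 11386 genes tested, 983 were higher and 449 lower in the 28 rich libraries. GB50423 stood at 1905 ± 801.7 CPM in the rich libraries (SD, n = 28), a log2 fold change of 11.10 ± 0.30 (SE, adjusted p = 7.28e-78), and its median in the other 152 was 0.235 CPM. GB50955 rose from 196 ± 14.3 CPM (SD, n = 152) to 402 ± 90.0 CPM (SD, n = 28), a log2 fold change of 1.03 ± 0.03 (SE, adjusted p = 3.95e-71). GB40164 fell by 1.75 ± 0.10 (SE, adjusted p = 2.54e-38), from 51.5 ± 16.4 to 11.9 ± 7.93 CPM (SD, n = 152 and 28), and GB50492 fell by 1.18 ± 0.10 on the log2 scale (SE, adjusted p = 2.70e-22). The other changes were mostly small: the median log2 fold change was 0.20 for the higher and -0.13 for the lower genes, and 52 higher and 12 lower genes exceeded 2-fold. Rich libraries numbered 14 among control and 14 among challenged bees, but 19 came from cR02, 4 from cR03 and 5 from cR21. Within colonies, 1102, 283 and 287 genes passed in cR02, cR03 and cR21. Of the genes called without a colony, 502 of 551 had the same direction in cR02, 931 of 1138 in cR03 and 1263 of 1449 in cR21 when that colony was left out, and 395, 417 and 470 of them had an unadjusted p below 0.05 in it, against 13.8, 28.5 and 36.2 from chance. The effect of DWV richness differed between colonies in 61 genes. With the pair as a block 729 genes passed, 670 of them among the 1432, and without colony cR02 551 passed. Across the 28 rich libraries, GB50423 had a Pearson's r of 0.473 (permutation p = 0.0107, adjusted over 5 genes 0.0536) and a Spearman's rho of 0.469 (permutation p = 0.0129, adjusted 0.0644) with the number of DWV reads per gene count, both on a log scale, and r was 0.514 without the 2 libraries farthest from the median number of DWV reads. The other 4 of the 5 genes, which like GB50423 had log2 fold changes over 7 with all colonies, had r of 0.287, 0.168, 0.0442 and -0.114 (permutation p = 0.139 to 0.827) and rho of 0.256, 0.152, -0.0115 and -0.0684 (permutation p = 0.188 to 0.954). Within colonies, the log2 fold changes of these 4 were 8.29 to 10.2 in cR02, 0.945 to 6.04 in cR03 and 5.24 to 8.76 in cR21. Those of GB50423 were 11.1, 11.6 and 10.3.

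**Figure D4:**
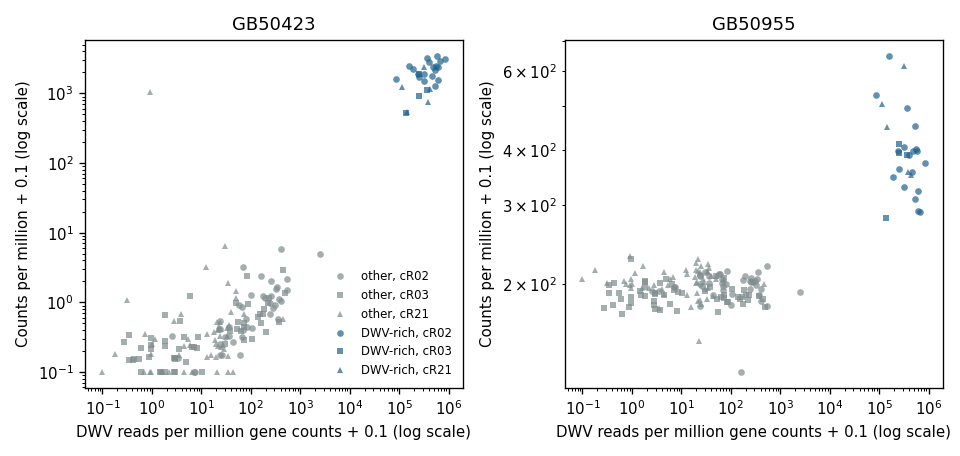
CPM plus 0.1 of GB50423 and GB50955 (y axes, log scale) against DWV reads per 1e+06 gene counts plus 0.1 (x axes, log scale) in each of the 180 libraries; blue points are the 28 DWV-rich libraries, grey points the other 152, and shapes are colonies. All rich libraries held at least 520.1 CPM of GB50423, while 1 of the other libraries held 1057 CPM and the rest at most 6.33 CPM.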

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

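Chosen after the result was seen were the test of the share of libraries with a high level of GB51815, the fits without those libraries, thinning, the fold after thinning as the measure for depth at 120 min, the percentage of mapped reads as a covariate and the removal of single libraries.

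The 10 genes lower in challenged bees at 120 min, and the 3 genes whose challenge effect differed between times (GB42549 and GB51815, adjusted p = 0.000189 for each, and GB42557, adjusted p = 0.00253), may rest on a few libraries. Without the 14 libraries over 10 CPM of GB51815, 0 of the 10 genes stayed past the threshold and their median log2 fold change went from -1.83 (median SE 0.40) to -0.67 (median SE 0.31), so the fold was smaller and no call remained, although for GB51815 itself and genes that vary with it this follows in part from how the libraries were chosen. Leaving out 14 random libraries of the same groups in 40 draws left a median of 16.5 genes at 120 min against 4 here, and 6 of the 40 draws left as few. After thinning, 7 of the 10 stayed past the threshold, and the median log2 fold change was -1.89 (median SE 0.44) against -1.83 (median SE 0.40), so the fold did not shrink, which argues against depth as the whole cause; the other 3, with log2 fold changes of -0.81, -2.05 and -2.84 against -0.80, -2.24 and -3.01, lost their calls with slightly larger SEs. Whether a challenge lowers the share of such libraries cannot be told apart from no change with 5 of 76 challenged and 9 of 76 control libraries (Fisher's exact test, two-sided p = 0.401, odds ratio 0.53, 95% interval 0.132 to 1.86).

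Among the genes higher in DWV-rich libraries, GB50423 could hold reads of the virus itself. In proportion to the mapped DWV reads, these would give a slope of 1 between its level and the DWV reads on log scales. Across the 28 rich libraries, colonies pooled, the slope was 0.411 (95% interval 0.103 to 0.720). Spread in the DWV reads that is unrelated to GB50423 also lowers such a slope, so viral reads are not excluded. Of the other 4 genes with log2 fold changes over 7, GB47318 had an interval that held 1 (-0.233 to 1.59). Those of the other 3 ended at 0.465 to 0.966, with the same limit, so the question stays open for all of these genes. Of the 983 genes, 88.2% stayed called and higher with all libraries thinned to the lowest total, which argues against depth as the whole cause. Without colony cR02, which held 19 of the 28 rich libraries, 38.0% stayed called and higher. The median log2 fold change of the 983 was then 85.6% of that with all colonies. This argues against cR02 as the whole cause, although the 983 were chosen with all colonies included. A response of the bee to the virus is an open hypothesis, as is anything else that differs between bees with and without much DWV, since infection was not assigned. The DWV difference itself differed between colonies in 61 genes, by a test of the interaction.

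The 19 genes higher at 30 min were weighed against depth, mapping and lane. Each first index sequence in the library titles at 30 min belonged to control or to challenged bees alone, so an effect of it cannot be told apart from challenge. Thinned to the lowest total, 18 of the 19 stayed past the threshold and higher. With the percentage of mapped reads as a covariate 16 stayed, so depth and mapping are each argued against as the whole cause. With the lane label as a term 18 stayed. As 89 of the 90 pairs carried 1 lane label, lane was nearly balanced over challenge and this term could change little by design. A response to the intruder may remain as a hypothesis, found and tested on the same data. Lanes L001 to L006 alone kept 14 of the 19 (median log2 fold change 0.43, median SE 0.09), while L00M alone, which at 30 min was the 20 cR03 libraries and 1 of cR21 before the DWV-rich ones were left out, called 0 genes by edgeR (728 at an unadjusted p below 0.05), with a median of 0.21 (median SE 0.13) for the 19.

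Other groupings of the same libraries bear on each count. In 100 splits of the libraries within time and colony, the real one included, only the real split gave as many genes at 30 min (22 against at most 19 in another split), at 120 min (27 against 25) and over all times (153 against 103). This argues against chance for these counts with all 152 libraries, but 100 splits cannot exclude it. At 120 min, however, leaving out 1 library gave a median of 16 genes (3 to 158), fewer than the highest other split. At 60 min all 100 splits gave at least the real count of 0, with at most 4. For the difference between times 9 of 100 splits gave 3 genes or more (highest other 15), and for the difference between colonies 6 of 100 gave 5 or more (highest other 17), so chance cannot be excluded for either. Colony labels gave 9582 genes against at most 24 in another split, 1 of 100 splits. For time among controls 4 of 100 splits gave 19 or more, and the highest other split gave 395, which points to a structure among the libraries. What that split follows was not tested, and lane labels were spread unevenly over times within colonies (all 20 cR02 libraries single at 30 min and all 20 L00M at 120 min), with 2 genes left with the lane term. For DWV 1 of 80 splits gave as many as 1432, with at most 24 in another. Where members of a pair were exchanged, so that each split parts as many pairs, the highest others were 4 at 30 min, 20 at 120 min and 6 over all times, and for the difference between times 18 of 100 splits gave as many, with a highest of 567.

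By the test of the interaction, 5 genes passed for a challenge effect that differed between colonies: GB41339 (adjusted p = 0.0118), GB42467 and GB45147 (0.0140 each), GB43422 (0.0175) and GB55613 (0.0316). As 6 of 100 splits gave as many, chance is not excluded, and 0 genes passed with the pair as a block, with limma-voom or without the 14 libraries (942, 844 and 943 at an unadjusted p below 0.05), although leaving out 14 random libraries also gave 0 in 11 of 40 draws.

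A total gene count of 26280621 in control 120 min cR03 replicate 7 stood apart from the other 8 libraries of its group, at most 20438305, and 19810467 in control 60 min cR02 replicate 10 stood apart from at most 13737228. The percentage of mapped reads was 83.4% in control 120 min cR21 replicate 3, 83.8% in control 60 min cR21 replicate 8 and 81.4% in challenged 30 min cR02 replicate 7, against at least 85.5%, 85.4% and 85.6% in the other libraries of those groups. In all, 5 of 36 groups and measures stood apart, and chance gives about 1 in 20.

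In the count rows outside genes, reads aligned to more than 1 place made up 0.222 percentage points more of the reads in DWV-rich libraries than in the others of the same groups, in 13 of 13 groups (permutation p = 1e-05, the smallest the permutations can give).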

How the results depend on the processing

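Thinning, the percentage mapped as a covariate, the fits without the 14 libraries over 10 CPM of GB51815 and the removal of single libraries were chosen after the data were seen. The counts over all genes called for colony differences stayed within 1.5 times of 9582 in each alternative run. For the other results the causes of the changes below were not tested, except where fewer libraries entered.

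At 30 min (22 genes) the count was 13 with all 180 libraries, 14 with complete pairs alone, 0 with the lane label L00M alone, 1 without cR02, 12 without cR21 and 12 without the 14 libraries. At 60 min (0 genes) it was 5 with all 180 libraries, 1 without cR03 and 3 with DESeq2. At 120 min (27 genes) it was 0 with limma-voom, 11 with no filter, 5 with a filter of 1 CPM in 50% of libraries, 3 with all 180 libraries, 5 with the pair as a replicate block, 17 with complete pairs alone, 2 with L00M alone, 67 with lanes L001 to L006 alone, 317 without cR02, 8 without cR03, 0 without cR21, 59 with DESeq2, 4 without the 14 libraries, 16 after thinning and 70 with the percentage mapped. Over all times (153 genes) it was 355 with all 180 libraries, 56 with the replicate block, 40 with complete pairs alone, 1 with L00M alone, 80 with lanes L001 to L006 alone, 293 without cR02, 5 without cR03, 8 without cR21, 243 with DESeq2, 35 without the 14 libraries and 389 with the percentage mapped.

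For the challenge effect differing between times (3 genes) it was 0 with limma-voom, the 1 CPM filter, all 180 libraries, the replicate block, without cR21 and without the 14 libraries, 8 without cR03 and 9 with DESeq2. For that differing between colonies (5 genes) it was 0 with limma-voom, the replicate block and without the 14 libraries, 2 with the 1 CPM filter and with complete pairs alone, 3 with the lane term and after thinning, and 19 with DESeq2. For time among controls (19 genes) it was 6 with limma-voom, 10 with no filter, 7 with the 1 CPM filter, 3 with all 180 libraries, 2 with the lane term, 10 without cR02, 53 without cR03, 11 without cR21, 34 with DESeq2, 1 without the 14 libraries and 5 after thinning. For DWV (1432 genes) it was 729 with the replicate block, 927 with L00M alone, 611 with lanes L001 to L006 alone and 551 without cR02.

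The replicate block did not change the counts at 30 and 60 min by over 1.5 times, and it was not fitted for colony differences or for time among controls. Leaving out 14 random libraries of the same groups gave counts as low as leaving out the 14 in 8 of 40 draws at 30 min, 15 over all times, 4 for the difference between times and 11 for that between colonies. Complete pairs without the block gave 17 genes at 120 min, so the fewer libraries do not account for all of the drop to 5 with the block. Among single genes 1 changed sign: GB50196 at 60 min, not past the threshold, was -0.52 with L00M alone. Of the values of named genes under an alternative, 337 kept their direction and side of the threshold, 110 no longer passed and 2 newly passed.

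Leaving out 1 library gave 16 to 32 genes at 30 min and 0 to 1 at 60 min, where GB50196 passed without control cR03 replicate 4 (3.89, adjusted p = 0.00316) and without challenged cR02 replicate 3 (3.35, adjusted p = 0.0496) and fell to 1.81 without challenged cR02 replicate 4 (adjusted p = 0.796) and 2.31 without challenged cR21 replicate 2 (adjusted p = 0.682), from 3.26. GB40340 (-0.35, adjusted p = 0.0614, and -0.34, adjusted p = 0.0554) and GB49758 (-0.26, adjusted p = 0.0691, and -0.25, adjusted p = 0.0614) no longer passed at 30 min without control cR02 replicate 8 and without challenged cR02 replicate 7, nor did GB40340 without control cR03 replicate 8 (-0.35, adjusted p = 0.0519) and GB49758 without challenged cR02 replicate 6 (-0.26, adjusted p = 0.0524). At 120 min it gave 3 to 158 genes and moved the count by over 1.5 times in 37 of 53 removals, with 3 genes without control cR02 replicate 5 and 158 without challenged cR21 replicate 1. Without control cR02 replicate 5, GB42549 (log2 fold change -3.0, adjusted p = 0.197) and GB51815 (-3.23, adjusted p = 0.168) no longer passed, nor did GB51815 without control cR03 replicate 4 (-3.23, adjusted p = 0.157). The 22 gene lists, and their alternatives with an estimated correlation, fry and the replicate block, were not run because no identifier matched the gene table. At these depths the smallest simulated change was recovered in 80.0% of genes at 30 min, so smaller changes can be missed.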

Other observations

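The following was noticed in the data and has no test against an explanation. Library control 60 min cR21 replicate 3 held 12 DWV reads, yet 1057 CPM of GB50423, within the range of the DWV-rich libraries (520.1 CPM at least) and far above the 6.33 CPM of the next of the other libraries. The deviations of this library from its group mean correlated with the DWV fold changes across the 1432 called genes, with r = 0.728, and with r = 0.415 without the 5 genes of log2 fold changes over 7. Genes are not independent replicates, and the highest of the other libraries reached 0.307 and the lowest rich library 0.533 on the second measure. Its directions matched in 55.7% of the 1432 genes. Its share of mapped reads was 85.9%, against a median of 70.3% in the rich libraries.

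GB50423 varied with DWV reads also below the threshold of 0.005. Across the 152 libraries r was 0.524 and rho 0.674 (permutation p = 1e-05 for both, the smallest the permutations can give, adjusted over 4 relations 1.33e-05), and r was 0.513 without the 2 libraries farthest from the median number of DWV reads. Within colonies r was 0.801 in cR02 (rho 0.799) and 0.692 in cR03 (rho 0.71), each with permutation p = 1e-05 for r and rho. In cR21 r was 0.169 (permutation p = 0.217) and rho 0.351 (permutation p = 0.00876), with r = 0.402 without the library above. These permutations treated libraries as independent. Control and challenged members of some pairs held similar DWV reads, such as 1431 and 1302 in replicate 3 of cR03 at 60 min. Others did not, such as 15 and 65 in replicate 1. The p-values can therefore be too small, and what links low DWV reads to GB50423 was not tested. Members of most pairs also shared a lane label and the second index sequence in the titles. Reads carried over between libraries were therefore not told apart from low levels of virus in the bee. No gene passed for the DWV share among the 152 libraries by edgeR, with 586 at an unadjusted p below 0.05.

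A set of 12 genes, GB51815 among them, was chosen for a correlation with GB51815 over libraries of more than 0.7. Of the 10 genes lower at 120 min, 3 belonged to this set. All 10 correlated positively with GB51815, with a median of 0.458 and at least 0.239. The genes higher at 120 min reached at most 0.147. Leaving out libraries by their level of GB51815 therefore bears on all 10 by choice.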
